A study of Mus musculus with 12 samples.

How the data were processed

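Kidney RNA of 12 female mice was measured, in 4 groups of 3 (WT control, WT NTS, KO control, KO NTS). Groups and replicate numbers came from the sample labels, and the design text states 3 mice per group, so replicates were taken as separate animals. RNA was extracted with a column kit, per the labels' protocols. The knockout animals are described as B6 and the wild-type animals as F1 littermates; whether their strain background is otherwise alike is not given in the sources used here. The instrument, its software and the assay lot or run of each sample are also not given in the sources used here.

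The values are a normalized signal per gene, as the authors deposited them. Per the file headers, each row is an endogenous gene (750), a housekeeping gene (20), a negative control (8) or a positive control (6), the layout of a panel that counts hybridized probes. The deposited signal was tested for its scaling: the geometric mean of the 20 housekeeping genes was 380.1 in 11 samples and 384.2 in KO control 3, and no value lay under the geometric mean of that sample's negative controls (10.02 to 15.11), which acts as a floor. The deposited table also gives, per gene, the percent of samples above the authors' threshold, which was not used. Values above the floor were whole multiples of 1 step per sample (0.955 to 1.09) in 99.5% to 100% of cases within a tolerance of 0.0055 of a step, so the signal carries probe counts divided by a factor. The unit was therefore not raw counts and not log2; count models were not run, and the plan's option for raw counts did not apply. A second deposited table held the same values (largest difference 0). All 12 sample columns were mapped to a label, with 0 columns left over.

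All tests were run with limma 3.58.1 in R 4.3.3 on log2(value + 1), on all 12 samples with 1 mean per group, no covariate and a variance trend (eBayes). Fold changes are on this scale and understate changes of low genes. Where a whole group lay at the floor, the floor also understates the fold on that scaling, and its size is uncertain. Genes were kept with a signal of at least 20 in at least 3 samples, which left 677 of 770. P-values were two-sided and adjusted by Benjamini-Hochberg over the genes of each comparison, with 0.05 as the threshold. There were 5 comparisons: the change after serum in WT and in KO, KO against WT in untreated and in treated kidneys, and the difference between both changes (interaction).

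For gene lists, 33 were fixed before the data were examined and 31 had at least 3 tested genes. Some lists share members, so their results are not independent. Each was compared with the other panel genes by camera with a preset correlation of 0.01, adjusted over the lists of a comparison. Camera works relative to the panel, so a list with a positive median can be called lower where most of the panel is higher. With the correlation estimated per list, 0 lists passed in any comparison. Genes named in the text were chosen by a rule fixed before the data were examined: the 8 highest and 8 lowest changes among called genes whose groups do not overlap (for the interaction without that condition), the 6 smallest p values where fewer than 6 genes passed, the 4 members with the smallest p of each list, and all members of the kidney injury and DNA sensing lists. The rule also named Aim2, which was not analysed here. Of the accessions on the panel, 748 of 770 matched a RefSeq gene table (GRCm38.p6), used for names alone; 6 symbols differ from current ones, such as Mb21d1 (Cgas) and Tmem173 (Sting1). Genes were read by 1 probe each, and near-identical relatives (the H2, Fcgr, Ifi200 and Ly6 families) may share signal.

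The steps were tested on simulated data with 677 genes, 200 of them changed, in 20 runs for each of the comparisons KO NTS against KO control and KO NTS against WT NTS. For KO NTS against WT NTS, 26.7% of 1.5-fold, 73.0% of 2-fold and 92.3% of 4-fold changes were recovered. Of these, 100% had the right direction, and 3.28% of calls were false. The simulated genes varied independently, with the same spread in every group and changes in random directions. The real genes are correlated and most real calls share a direction, so these rates need not hold for the real data. The summed endogenous signal, 596307 to 1346839 per sample, is after scaling and is not a depth; 53 to 140 genes per sample lay at the floor, and the number of samples limits the precision.

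The alternatives were another pseudocount, other filters, 4 other scalings (common reference genes, median centring, quantile normalization and positive controls), other variance models, the replicate number as a block, only the 2 groups compared, a 2-fold minimum, each sample left out in turn, and other list tests. Scaling on the positive controls, leaving out WT NTS 1 and WT control 1 together, leaving out genes at the floor in a whole group, and median centring for the lists were chosen after seeing the data.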

Results

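Kidney RNA was measured on a targeted panel of 750 endogenous and 20 housekeeping genes in 12 female mice, 3 in each of 4 groups. Wild-type (WT) animals and animals lacking Aim2 (KO), a cytosolic sensor of double-stranded DNA that builds an inflammasome, were either left untreated or given nephrotoxic serum (NTS). This serum holds antibodies against the glomerular basement membrane and induces an immune glomerulonephritis. The treated kidneys are labelled day 9, and the labels give no day for the untreated ones. The design asks how the kidney responds to the serum in each genotype, whether untreated kidneys differ by genotype, and whether the response itself differs. The level of Aim2 was not analysed here, so the genotype labels were not checked against the targeted gene. The summed signal of the endogenous genes ranged from 596307 to 1346839 per sample. Spp1, which encodes the matrix protein osteopontin, made up 7.92% ± 1.11 of that sum in WT control, 23.9% ± 15.4 in WT NTS, 7.73% ± 1.04 in KO control and 53.4% ± 1.38 in KO NTS (SD, n = 3). Of 770 genes, 677 had enough signal to be tested.

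In WT kidneys, some genes of cell division, chemokines and MHC class II rose after nephrotoxic serum, a minority of each list, and 0 list calls held with an estimated correlation. Mki67, a marker of dividing cells, rose from 102 ± 84.8 to 1035 ± 573 (mean signal ± SD, n = 3 per group; 11.2-fold, log2 change 3.49, SE 0.52, adjusted p = 0.00343). Birc5, a mitotic survivin, rose from 52.2 ± 30.8 to 447 ± 167 (8.81-fold, adjusted p = 0.00138), and the chemokine Ccl20 rose from 14.8 ± 0.244 to 100 ± 48.2 (adjusted p = 0.00343), with 2 of 3 WT controls at the background floor. Egf, made in the distal tubule, fell from 25765 ± 6025 to 9350 ± 3878 (log2 change -1.51, SE 0.30, adjusted p = 0.0158). Aldoc, a glycolytic aldolase, had a log2 change of -2.10 (adjusted p = 0.00448).

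Among the gene lists, 4 of 12 cell cycle genes rose and 1 fell in WT kidneys. Rrm2, a subunit of the enzyme that makes deoxynucleotides, rose 3.87-fold, and Cdc20, an activator of the anaphase-promoting complex, rose 4.86-fold. Adjusted over the list alone, 5 rose and 1 fell, and the list stood above the other panel genes (camera adjusted p = 0.00185; adjusted p = 0.600 with an estimated correlation). In the list of the p53 pathway, cell cycle inhibitors and DNA repair, 4 of 24 genes rose, among them Brca1 (2.73-fold). That list did not stand above the panel (camera adjusted p = 0.399). Of 12 MHC class II genes, 4 rose, or 8 adjusted over the list alone (camera adjusted p = 0.000779; adjusted p = 0.600 with an estimated correlation). These were the class II chain H2-Ab1, the invariant chain Cd74, the peptide loading factor H2-DMb2 and the protease Ctss, with log2 changes of 1.33, 1.25, 2.28 and 1.18. H2-Ab1 and Cd74 passed in 2 and 3 of 5 scalings. Of 10 kidney injury genes, 3 rose, or 8 adjusted over the list alone: the stress-induced transcription factor Atf3 (log2 change 1.55), the monocyte attractant Ccl2 (2.14) and Spp1 (1.65). That list had a camera adjusted p of 0.00135 (adjusted p = 0.600 with an estimated correlation). Its mean log2 level above the WT control mean was 2.17 in WT NTS 1 against 0.78 and 0.82 in the other WT NTS samples. Spp1 passed in 3 of 5 scalings. Atf3 missed without WT NTS 1 or WT control 3, and Ccl2 without WT control 1 or 3.

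Of 38 chemokine genes, 5 rose in WT kidneys, or 7 with 1 lower adjusted over the list alone: Ccl20, Ccl2, Ccl9, Ccl5, which attracts T cells, and Cxcl10, an interferon-induced chemokine. Their log2 changes were 2.53, 2.14, 2.03, 2.05 and 1.71, and the list had a camera adjusted p of 0.0207 (adjusted p = 0.691 with an estimated correlation). Ccl5 lost its call in 8 and Cxcl10 in 5 of 25 alternatives, both without WT NTS 1, WT control 1 or WT control 3. The mean log2 level of the list above the WT control mean was 1.06 in WT NTS 1, 0.30 in WT NTS 2 and 0.44 in WT NTS 3. The list of Fc receptors and the immune complex response had 2 of 7 genes higher, the antibody receptors Fcgr1 and Fcgr4, or 4 adjusted over the list alone. Fcgr1 lost its call in 12 and Fcgr4 in 5 of 25 alternatives, both without WT NTS 1, WT control 1 or WT control 3. Their log2 changes were 1.68 and 1.07, and the camera adjusted p was 0.0129 (adjusted p = 0.453 with an estimated correlation). Complement had 2 of 7 genes higher, or 4 adjusted over the list alone, with C1qb, a chain of the first complement component, at a log2 change of 0.98 (camera adjusted p = 0.0207; adjusted p = 0.600 with an estimated correlation). C1qb passed in 2 of 5 scalings, and 0 complement genes were called on common reference genes or on the positive controls. The list of genes near Aim2 on chromosome 1, which holds immune receptors, had 2 of 9 genes higher, or 4 adjusted over the list alone (camera adjusted p = 0.00254; adjusted p = 0.600 with an estimated correlation). In the NK cell list, 1 of 9 genes rose, the receptor gene Klrd1, or 2 adjusted over the list alone (camera adjusted p = 0.0357; adjusted p = 0.600 with an estimated correlation). The Wnt list lay below the other genes, with 0 of 15 genes called and a median log2 change of -0.35; 5 were lower with median centring and 2 with quantile normalization. So did the Notch and Hedgehog list, with 1 of 13 called (Gas1, a Hedgehog co-receptor, log2 change -0.63). Both had a camera adjusted p of 0.0207 (adjusted p = 0.600 with an estimated correlation), and adjusted over the list alone these counts were 0 and 1. Gas1 passed in 2 of 5 scalings, and the Notch and Hedgehog list had 4 genes lower with median centring and 0 with the other 3. Of 17 T cell markers, 29 interferon-stimulated genes and 9 genes of cytosolic DNA sensing and the inflammasome, 0, 1 and 0 passed the test.

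In all, 54 of 677 genes passed an adjusted p of 0.05 in WT kidneys with limma, 37 higher and 17 lower, and 152 had an unadjusted p under 0.05. The samples of both groups did not overlap for 134 genes (19.8%), against 10% by chance. With only the samples of these groups in the fit the count was 2 genes. Without WT NTS 1 it was 27, and without WT control 1, 2 or 3 it was 19, 94 or 9. Without KO NTS 1, 2 or 3 it was 32, 35 or 33, and without KO control 1, 2 or 3 it was 29, 28 or 35. With samples centred on the median gene, 31 were higher and 47 lower, with quantile normalization 30 and 21. Scaling on common reference genes gave 27 and 7, and scaling on the positive controls 33 and 3.

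In KO kidneys, the serum was followed by a larger set of changes. Ccl20 rose from 15.9 ± 2.4 to 648 ± 242 (log2 change 5.21, SE 0.38, adjusted p = 7.39e-06). The neutrophil attractant Cxcl1 rose from 15 ± 3.05 to 595 ± 173 (adjusted p = 0.000147). Both were at the background floor in 2 of 3 KO controls, so the size of these changes is uncertain. Lif, a cytokine of the interleukin-6 family, rose 22.6-fold, with 1 of 3 KO controls at the floor. Mmp7, a matrix protease of injured tubules, was at the background floor in all 3 KO control samples and reached 302 ± 76.9. Its log2 change against that floor was 4.32, a size that the floor makes uncertain. It ranged from 3.55 to 4.52 over the 5 scalings. Spp1 rose from 47837 ± 6028 to 717080 ± 21707 (15.1-fold, adjusted p = 0.000147), while Egf fell from 22766 ± 3885 to 1515 ± 402 (log2 change -3.93, SE 0.30, adjusted p = 7.39e-06).

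**Figure D1:**
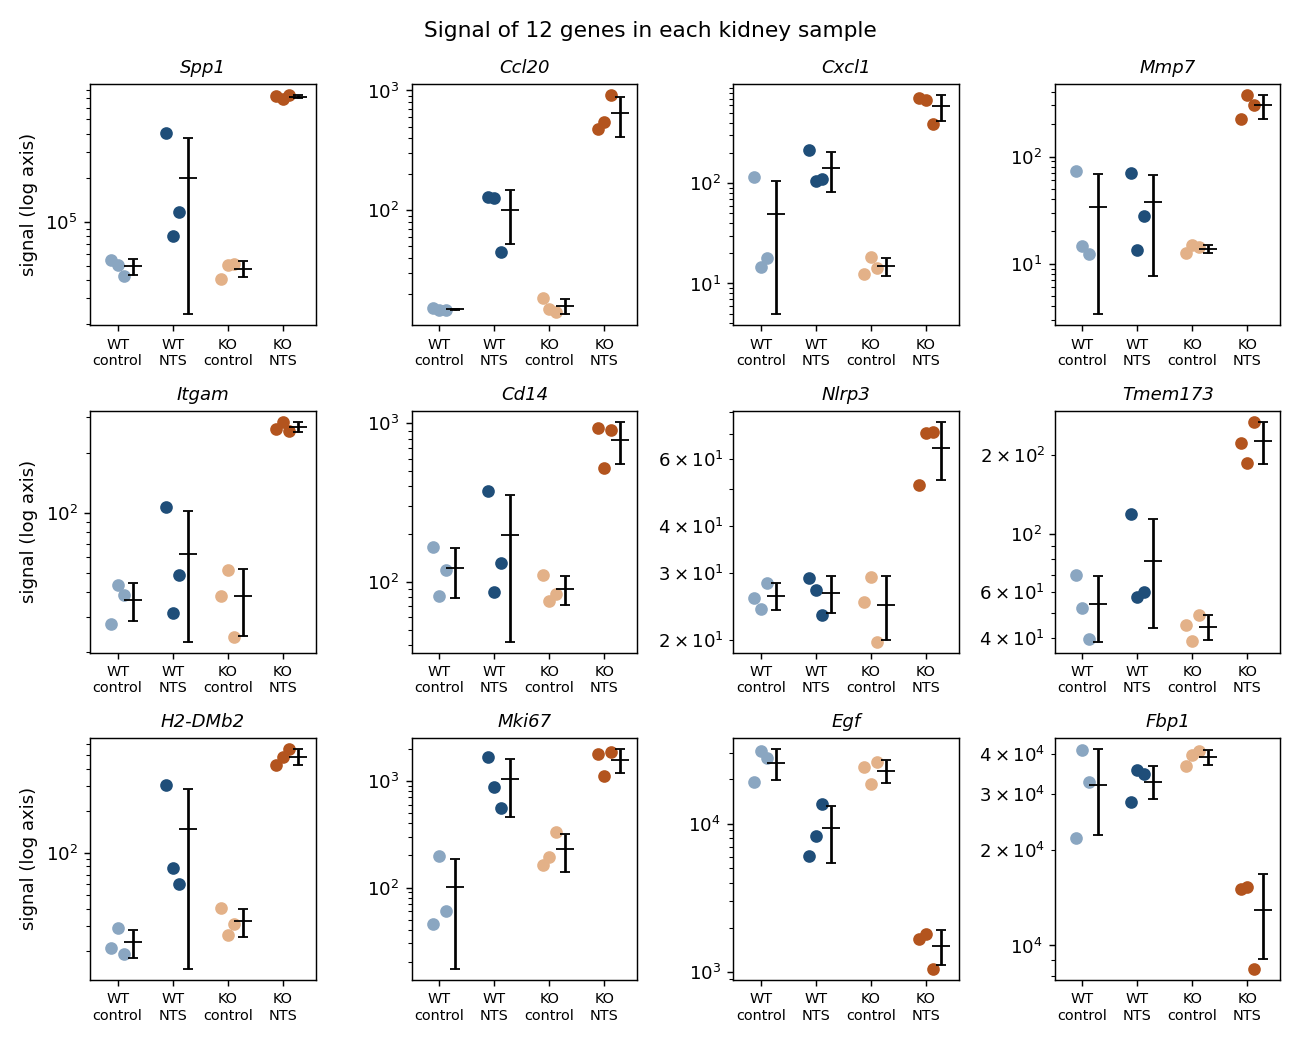
Signal of 12 genes (log axis) in each of the 12 kidney samples by group; dots are single mice and the bar beside them is the mean with its SD (n = 3; the lower arm is shortened where it would reach 0). Spp1 averaged 717080 in KO NTS and 199380 in WT NTS, and Egf averaged 1515 and 9350.

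Of 10 kidney injury genes, 9 rose in KO kidneys (median log2 change 3.27; camera adjusted p = 0.000861; adjusted p = 0.668 with an estimated correlation), and 9 also adjusted over the list alone. They included Il34, a ligand of the macrophage growth factor receptor, the adhesion molecule Vcam1 and the transcription factor Myc (log2 changes 3.62, 3.59 and 2.5). Cd44 had a log2 change of 0.75 (adjusted p = 0.136), which was -0.02 with median centring. Of 30 fixed members of the list of proximal tubule and nephron transport markers, 3 were on the panel. All 3 fell, also adjusted over the list alone. Among them were Egf, which is made in the distal tubule and also counts in the growth factor list, and the gluconeogenic enzyme Fbp1 (log2 change -1.65). This list had a camera adjusted p of 0.000861 (adjusted p = 0.263 with an estimated correlation). Of 20 pro-inflammatory genes, 15 rose and 1 fell, the same counts adjusted over the list alone (median log2 change 1.48; camera adjusted p = 0.018; adjusted p = 0.668 with an estimated correlation).

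Macrophage markers rose in 13 of 18 cases, also adjusted over the list alone (camera adjusted p = 0.0209; adjusted p = 0.668 with an estimated correlation). Examples were Itgam, an integrin chain of myeloid cells (38.1 ± 14 to 268 ± 15.2, 7.20-fold), the antibody receptor Fcgr1 (8.06-fold) and the lipopolysaccharide co-receptor Cd14 (8.48-fold). Of 7 complement genes, 6 rose, or 7 adjusted over the list alone, with C7, a component of the membrane attack complex, 4.40-fold higher (camera adjusted p = 0.0209; adjusted p = 0.668 with an estimated correlation). Of 12 MHC class II genes, 11 rose, also adjusted over the list alone, including H2-DMb2 (14.7-fold) and the co-stimulatory molecule Cd80 (5.44-fold), with a camera adjusted p of 0.0213 (adjusted p = 0.668 with an estimated correlation). With median centring, 9 macrophage markers were higher and 3 lower, 6 complement genes higher, 5 MHC class II genes higher and 1 lower, and 10 pro-inflammatory genes higher and 1 lower.

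Other lists had many members called in KO kidneys without standing above the rest of the panel. Of 29 interferon-stimulated genes, 20 rose and 1 fell, or 22 and 1 adjusted over the list alone (camera adjusted p = 0.0696), among them Cxcl10 (5.85-fold) and Oas2, a sensor of double-stranded RNA (4.56-fold). The interferon list had 5 higher and 3 lower with median centring and 10 and 3 with quantile normalization, and 5 genes, Cxcl10 and Oas2 among them, rose under all 5 scalings. Chemokine genes rose in 18 of 38 cases and fell in 2, also adjusted over the list alone, with Cxcl5 higher (2 of 3 KO controls at the floor) and the stromal chemokine Cxcl12 at a log2 change of -1.69. Median centring gave 15 higher and 10 lower and quantile normalization 16 and 9, and with the former the median of the chemokine list turned from 0.73 to -0.04. Cell cycle genes rose in 8 of 12 cases and fell in 1, also adjusted over the list alone, and Ccne1, a cyclin of S phase entry, rose 4.53-fold. Of 9 DNA sensing and inflammasome genes, 4 rose, also adjusted over the list alone: the adaptor Tmem173 (Sting1, 4.99-fold), the sensor Mb21d1 (Cgas, 2.84-fold), the inflammasome sensor Nlrp3 (2.53-fold) and the MHC class I regulator Nlrc5 (2.20-fold). The median of this list turned from 0.44 to -0.33 with median centring, where Nlrp3 and Nlrc5 were no longer called. Nlrc5 also missed without KO NTS 3 and without KO control 2. Casp1 and Il18, the inflammasome protease and one of its substrates, had log2 changes of 0.44 and 0.29 (adjusted p = 0.272 for both). Both lay below 0 with median centring, and with quantile normalization Il18 was called lower at -0.66 (adjusted p = 0.0305). The genes with the largest falls also included Prlr, the prolactin receptor (log2 change -2.67), and Id4 (-1.90), an inhibitor of DNA binding. Further ones were the transferrin receptor Tfrc (-1.62) and the growth hormone receptor Ghr (-1.49). Tfrc is among the 20 housekeeping genes on which the signal was scaled. Of these, Sdha (-1.10) and Oaz1 (-0.52) were also called lower, and Stk11ip (0.95), Gusb (0.69) and G6pdx (0.59) higher.

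In KO kidneys 326 genes passed the test, 268 higher and 58 lower (82.2% higher), 227 of them by at least 2-fold, and the samples of both groups did not overlap for 444 genes (65.6%, against 10% by chance). In simulated data of this comparison with 677 genes, 70.6% of 2-fold and 32.0% of 1.5-fold changes were recovered, and 3.34% of calls were false. Those simulated genes were independent and changed in random directions, so the share of false calls in the real data may differ. The balance of higher to lower depended on the scaling. The median log2 change was 0.42 on the housekeeping genes, 0.50 on common reference genes, 0.63 on the positive controls, -0.35 with median centring and -0.19 with quantile normalization. Median centring gave 134 higher and 269 lower genes, quantile normalization 159 and 214, and the positive controls 270 and 18. Under all 5 scalings 126 genes were higher and 18 lower, and 2 genes were called in opposite directions by different scalings.

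Untreated kidneys of the genotypes differed in 0 of 677 single genes with limma (smallest adjusted p = 0.575), and 57 genes had an unadjusted p under 0.05. The samples did not overlap for 79 genes (11.7%, against 10% by chance). Il18bp, a secreted binding protein of interleukin 18, was at 190 ± 112 in WT and 552 ± 148 in KO (log2 difference 1.65, SE 0.43, adjusted p = 0.575). Slamf7, a receptor of lymphocytes, was at 36.1 ± 17 and 72.1 ± 7.59, and Ptgs2, a prostaglandin synthase, at 198 ± 237 and 22.2 ± 8.34, with the same adjusted p. The WT mean of Ptgs2 rested on WT control 1, at 469.98 against 29.9 and 95.29.

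As lists, MHC class II (median log2 difference 0.42, 0 of 12 genes called, also adjusted over the list alone) and genes near Aim2 (0.48, 0 of 9 called, or 1 adjusted over the list alone) lay above the other genes in untreated KO kidneys. Their camera adjusted p values were 0.0114 and 0.0476, and both had an adjusted p = 0.821 with an estimated correlation. H2-Ab1 was at 2619 ± 1548 in WT and 4411 ± 676 in KO, and Ifi203, a neighbour of Aim2 from the same gene family, at 174 ± 56 and 284 ± 57.8. With each of the 12 samples left out in turn, the list near Aim2 passed in 3 cases and missed in 9 (camera adjusted p from 0.0153 to 0.109). MHC class II passed in all 12 (0.00215 to 0.0496), but with fry its adjusted p was 0.544. Its mean log2 level above the WT control mean was -0.37, 0.49 and -0.11 in WT control 1, 2 and 3. In KO control 1, 2 and 3 it was 0.56, 0.41 and 0.55, so WT control 2 lay within the KO range. Without WT control 2 there were 22 single genes called. This sample had correlations of 0.988, 0.989 and 0.994 with the KO controls and of 0.951 and 0.979 with the other WT controls.

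After nephrotoxic serum, 9 of 10 kidney injury, 14 of 18 macrophage and 13 of 20 pro-inflammatory genes were higher in KO than WT kidneys. With median centring these counts were 7, 8 and 6, and 0 list calls held with an estimated correlation. The lists overlap: Csf1, Icam1 and Vcam1 count as both kidney injury and pro-inflammatory genes, and Ccl2 as both a kidney injury and a chemokine gene. The macrophage list also shares Itgam with complement, Cd80 with MHC class II and Cd14 with the Toll-like receptors, so these counts partly repeat the same genes. Mmp7 was at 37.5 ± 29.8 in WT and 302 ± 76.9 in KO (log2 difference 3.25, SE 0.64, adjusted p = 0.00505). Ccl20 was 6.81-fold higher (adjusted p = 0.00356), Cxcl5 5.23-fold, Vcan, a matrix proteoglycan, 5.19-fold, and Itgam 4.83-fold (62.2 ± 39.6 against 268 ± 15.2, adjusted p = 0.005). Egf was lower (9350 ± 3878 against 1515 ± 402, log2 difference -2.58, SE 0.30, adjusted p = 0.00142), as was Fbp1 (32818 ± 3982 against 12901 ± 3862, log2 difference -1.39). These WT NTS means carry a wide spread, with Spp1 taking 41.5% of the endogenous signal in WT NTS 1 and 13.3% and 16.8% in WT NTS 2 and 3.

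Of 18 macrophage markers, 14 were higher in KO NTS, also adjusted over the list alone (median log2 difference 1.51; camera adjusted p = 0.00934; adjusted p = 0.724 with an estimated correlation). They included Siglec1, a sialic acid receptor (4.07-fold), the mannose receptor Mrc1 (3.84-fold) and Trem2, a lipid receptor (3.41-fold). Of 10 kidney injury genes, 9 were higher, also adjusted over the list alone (median 1.74; camera adjusted p = 0.0108; adjusted p = 0.724 with an estimated correlation). Among them, Spp1 was 4.62-fold, Vcam1 4.58-fold and Csf1, a macrophage growth factor, 3.48-fold higher. Complement had 6 of 7 genes higher, also adjusted over the list alone, C7 by 2.98-fold and C1qa by 2.29-fold. Of 20 pro-inflammatory genes, 13 were higher, or 14 adjusted over the list alone, and of 12 MHC class II genes 9, or 10 adjusted over the list alone. Interferon-stimulated genes were higher in 16 of 29 cases, or 18 adjusted over the list alone, with Oas2 3.25-fold and Ifih1, a sensor of viral RNA, 2.22-fold higher. These 4 lists had a camera adjusted p of 0.0301 each, with an adjusted p = 0.724 with an estimated correlation for the first 3 and 0.728 for the interferon list. With median centring 1 interferon-stimulated gene was higher and 1 lower, with quantile normalization 5 and 1, and Oas2 alone was higher under all 5 scalings. Median centring left 4 complement and 3 MHC class II genes higher. Of 20 matrix genes, 10 were higher, or 11 adjusted over the list alone (camera adjusted p = 0.0471; adjusted p = 0.724 with an estimated correlation). Thbs1, a matricellular protein, was 2.46-fold and Pdgfrb, a receptor of mesangial cells and pericytes, 2.44-fold higher.

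Of the 3 nephron markers on the panel, 2 were lower, Egf and Fbp1, also adjusted over the list alone (camera adjusted p = 3.52e-05, or 0.103 with an estimated correlation). The list of 8 common reference genes lay below the other genes (median -0.06 against 0.45 for all tested genes; camera adjusted p = 0.038; adjusted p = 0.434 with an estimated correlation). In it 1 gene was higher and 2 were lower, the same adjusted over the list alone. The deposited signal was scaled on the housekeeping genes, which holds such genes near 0. This list call therefore restates the shift of the panel and is no separate result. Sdha, a mitochondrial dehydrogenase used for scaling, had a log2 difference of -0.70. Kdr, Angpt1 and Vegfa were lower (log2 differences -0.90, -0.75 and -0.66), each passing in 4 of 5 scalings. The list of endothelial and adhesion molecules had 4 of 12 genes higher and 1 lower, also adjusted over the list alone, and that of growth factors 6 of 22 higher and 5 lower, or 8 and 5. With median centring these lists had 2 higher and 2 lower, and 3 and 7, and on the positive controls 3 and 0, and 5 and 1. Of 9 DNA sensing and inflammasome genes, 5 were higher, also adjusted over the list alone: Tmem173 (2.98-fold), Mb21d1 (2.38-fold), Nlrp3 (26.5 ± 2.97 against 64.1 ± 11.2, 2.35-fold), Nlrc5 (2.16-fold) and the cytokine Il1b (2.11-fold). Of these, Tmem173 passed in all 5 scalings. The DNA sensing list did not stand above the panel (camera adjusted p = 0.641). With median centring 2 of its genes were higher and 1 lower. Nlrc5 and Il1b missed without WT NTS 2, WT NTS 3, KO NTS 1 or KO NTS 3. Casp1 had a log2 difference of 0.36 (adjusted p = 0.391), below 0 with median centring and with quantile normalization. Il18 had one of -0.06 (adjusted p = 0.854), above 0 when scaled on common reference genes or positive controls and called lower with quantile normalization at -0.77 (adjusted p = 0.0299). Of 12 cell cycle genes, 3 were higher, also adjusted over the list alone, with Ccne1 1.89-fold higher; with median centring 0 passed and the list median turned from 0.44 to -0.15.

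**Figure D2:**
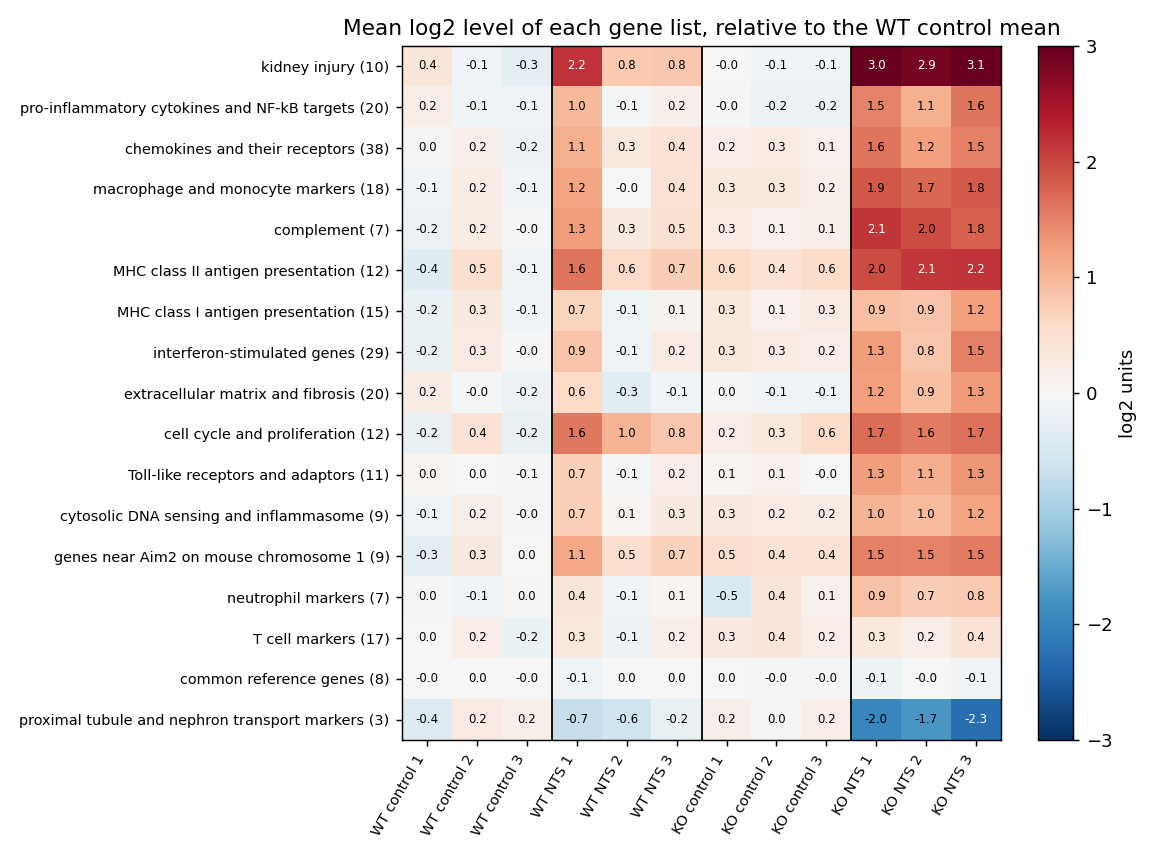
Mean log2 level of 17 gene lists (number of tested genes in brackets) in each of the 12 samples, relative to the WT control mean, from blue (lower) to red (higher). The colours are on the housekeeping scaling, and the median centred medians of the T cell and cell cycle lists after serum were lower in KO than in WT.

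In this comparison 227 genes passed, 211 higher and 16 lower in KO NTS (93.0% higher), and the samples did not overlap for 288 genes (42.5%, against 10% by chance). The balance followed the scaling. Median centring gave 77 higher and 97 lower and quantile normalization 90 and 97, with the median log2 difference moving from 0.45 to -0.14 and -0.07; on the positive controls it was 0.64. Under all 5 scalings 69 genes were higher and 3 lower. Leaving out WT NTS 1 gave 329 genes, and leaving out WT NTS 2, WT NTS 3, KO NTS 1 or KO NTS 3 gave 137, 129, 151 or 138. The 9 lists, the common reference genes among them, became 5 without WT NTS 3.

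By the interaction test, the response to serum differed between genotypes for 70 genes, 65 with a higher and 5 with a lower change in KO. This count is weak: 0 genes passed in 9 of the 12 fits with 1 sample left out, and 6 of 100 splits of the samples, the real one included, gave as many. The exceptions were the fits without WT NTS 1 (207 genes), without KO NTS 2 (42) and without WT control 2 (89). The smallest adjusted p was 0.0351, and 194 genes had an unadjusted p under 0.05. Vcan had an interaction of 3.63 (log2, SE 0.74) and Edn1, a vasoconstrictor peptide, of 2.52 (SE 0.58), each with an adjusted p of 0.0351. Mmp7 and Ccl20 passed at the same adjusted p (4.01 and 2.68), but their size is uncertain, as 5 and 4 of the 6 control samples lay at the floor. Egf and Fbp1 had interactions of -2.42 (SE 0.43) and -1.73 (SE 0.38) at the same adjusted p. WT control 1 contributed to the Mmp7 value, with a signal of 73.55 against 14.72 and 12.41 in the other WT controls. Part of the Vcan interaction came from a lower level in untreated KO than in untreated WT kidneys. Over the 5 scalings the Vcan interaction ranged from 3.129 to 3.709, and its log2 difference between KO NTS and WT NTS from 1.725 to 2.557.

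Of 10 kidney injury genes, 5 passed the interaction test, or 9 adjusted over the list alone (median 1.78; camera adjusted p = 0.00823; adjusted p = 0.790 with an estimated correlation). Of 20 pro-inflammatory genes, 6 passed, or 12 adjusted over the list alone, among them Birc3 and Tnfaip3, feedback regulators of NF-kB (1.47 and 1.36; camera adjusted p = 0.0189; adjusted p = 0.790 with an estimated correlation). With median centring 0 kidney injury and 1 pro-inflammatory gene passed, with quantile normalization 1 and 3, and on the positive controls 0 of either list. The nephron list had 2 of its 3 genes on the panel, Egf and Fbp1, with a lower change, also adjusted over the list alone (camera adjusted p = 0.000174, or 0.153 with an estimated correlation). Scaled on the positive controls, 9 genes passed (7 higher, 2 lower), with median centring 20 (12 higher, 8 lower) and with quantile normalization 46 (20 higher, 26 lower); under all 5 scalings 5 genes were higher and 2 lower.

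Across the 677 genes, which are not independent replicates, the log2 changes in WT and KO had a Pearson correlation of 0.66 and a Spearman correlation of 0.63; these responses share no samples. All 37 genes that rose in WT also rose in KO, against 14.65 for independent lists, and 7 of 17 that fell in WT also fell in KO, against 1.456. Without WT NTS 1 the correlation was 0.48, without WT control 2 it was 0.52 and without WT control 1 it was 0.77. The larger change, in either direction, was in KO for 493 of 677 genes (72.8%).

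**Figure D3:**
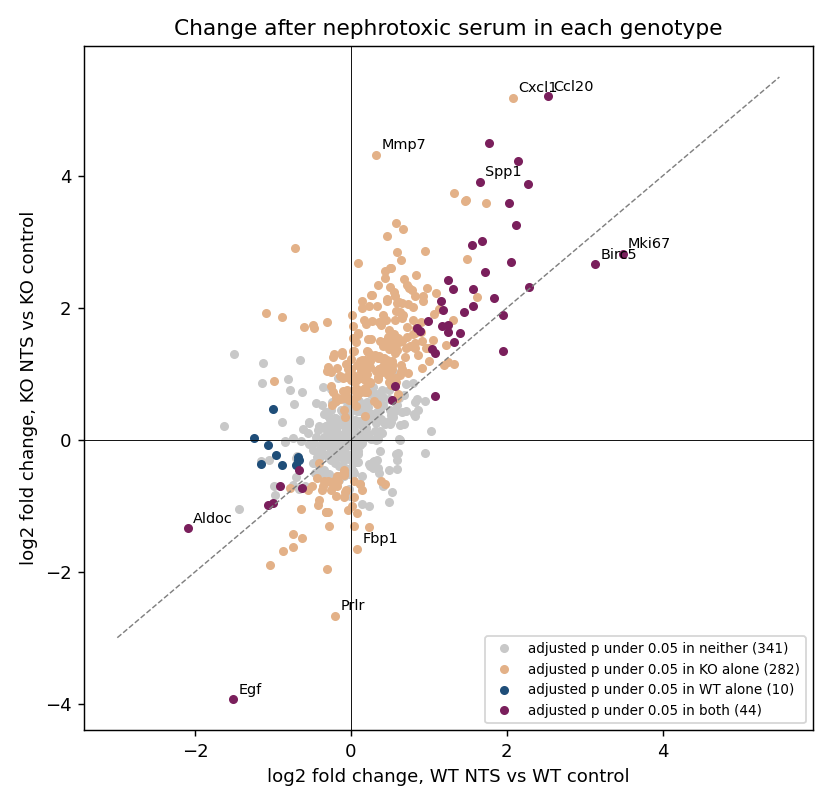
Each point is 1 of 677 genes, with the log2 change after serum in WT (x axis) and in KO (y axis); colours mark where it passed an adjusted p of 0.05 and the dashed line marks equal change. Ccl20 lies at 2.53 and 5.21, and Egf at -1.51 and -3.93.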

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

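Of the tests below, those on Spp1, on the positive controls, on a swap and on a single wrong label were chosen after the result was seen.

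The response to serum differed between KO and WT by the interaction test for 65 genes with a higher and 5 with a lower change in KO. In 6 of 100 splits of the samples as many genes passed (70 in the real split, up to 123 in others), so chance is not excluded. For the lists, 24 of 100 splits gave as many as the 3 that passed (up to 8 in others), and chance is not excluded there either. The log2 interactions were 4.01 for Mmp7 (of uncertain size, with 5 of 6 controls at the floor), 3.63 for Vcan, 3.11 for Cxcl1, 2.72 for Lif, 2.68 for Ccl20, 2.62 for Cd14, 2.60 for Cxcl2, 2.52 for Edn1, 2.26 for Spp1 and for Itgam, 2.16 for Il34, 2.02 for Siglec1, 1.82 for Tmem173, 1.71 for Csf1, 1.62 for Ccne1, 1.47 for Birc3, 1.36 for Tnfaip3 and 1.32 for Nlrp3. Ccl20 and Cxcl1 also had control samples at the floor, so their size is uncertain too. Cxcl1 passed in 2 of 5 scalings, and its signal in WT control 1 was 114.63 against 14.72 and 17.8 in the other WT controls. Lower changes in KO were -2.42 for Egf, -1.73 for Fbp1, -1.34 for Kdr, -1.02 for Angpt1 and -0.90 for Vegfa. The list medians were 1.78 for kidney injury, 1.01 for pro-inflammatory genes and -1.73 for proximal tubule and nephron transport markers (Egf and Fbp1 among them). None of the 23 named genes kept its call under every alternative, and without WT NTS 2, WT NTS 3, KO NTS 1, KO NTS 3, WT control 1, WT control 3 or any KO control sample 0 genes passed.

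After serum, 211 genes were higher and 16 lower in KO than in WT, and a bound written before the test said that the authors' housekeeping scaling could account for this if median centring left at most a 50% share of the higher genes; it left 77, with 97 lower, so the bound was met. The test was judged void only after that value was seen, because centring balances higher and lower genes whatever the source, and the scaling therefore cannot be told apart from a change in most panel genes. Scaled on the positive controls instead, 213 genes were higher and 4 lower, which argues against falling housekeeping genes as the source if equal RNA was loaded, which the sources used here do not give. The summed signal without Spp1 was 71271 higher in KO NTS, which decides nothing on signal lost to Spp1, as these sums were already scaled on the housekeeping genes (judged void after it was seen). Genotype remains open as an untested biological explanation.

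On the first principal component (67.5% of the variance) WT NTS 1 lay at 11.3, WT NTS 2 and 3 at -5.03 and -4.47, and the lowest KO NTS sample at 18.0. Every KO NTS sample lay above WT NTS 1, the nearest by 6.67. These positions were seen before the test of a swap with a KO NTS sample was chosen. That test also presumes that a WT mouse lies near WT NTS 2 and 3, so a swap is not decided. WT NTS 1 correlated better with every KO NTS sample (0.968 to 0.974) than with WT NTS 2 and 3 (0.963 and 0.965). A single wrong genotype label cannot be told apart from a strong response of this mouse, because 0 values of the targeted gene were used. A graded response, with this mouse further along it, stays open too: its change from the WT control mean had a correlation across genes of 0.776 with the KO response and a slope of 0.664 (0.504 and 0.207 for WT NTS 2, 0.364 and 0.188 for WT NTS 3), under the bound of 0.8 written before. Genotype stays open, and no test separated it from these.

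WT control 1 stood apart from its group in 55 genes by at least 2-fold (34 higher, 21 lower), WT control 2 in 68 and WT control 3 in 13, against 12, 7 and 8 for the KO controls, and 2 lists differed at baseline; WT control 2 correlated better with every KO control (0.988 to 0.994) than with its own group (0.951 and 0.979). Without WT control 1 there were 4 lists that passed, including both of these at an adjusted p of 0.0477; that met the bound written beforehand against this sample as the source. With each sample left out MHC class II passed in all 12 fits (camera adjusted p 0.00215 to 0.0496) but genes near Aim2 in 3 (up to 0.109). The verdict was changed to open after this was seen, so for both lists together WT control 1 cannot be told apart from a genotype difference. The MHC class II level of WT control 2 (0.49) lay within the range of the KO controls (0.41 to 0.56). For 85.5% of the 55 genes the higher level was over 3 times the floor, which met the bound written beforehand against low signal. That test cannot decide it, because genes at least 2-fold apart have a higher level well off the floor by choice. The lower level was not tested, and for Mmp7 and Il23r it was the floor itself in WT control 2 and 3 (14.72 and 12.41). Genotype, the strain background that goes with it and a wrong label of WT control 2 were not tested.

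For each comparison of 3 samples with 3, the 10 possible splits are too few for a share under 0.05. In WT 54 genes and 10 lists passed, and up to 5 and 4 in the other splits. In KO it was 326 genes and 6 lists, and up to 0 and 6. For untreated kidneys it was 0 genes and 2 lists, and up to 0 and 1, and for treated kidneys 227 genes and 9 lists, and up to 19 and 6.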

How the results depend on the processing

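Tests with scaling on the positive controls, with WT NTS 1 and WT control 1 left out together, without genes at the floor in a whole group and, for the lists, with median centring were chosen after the result was seen; the others were fixed before the data were examined. The KO response had the steadiest total, but not direction, with 134 higher and 269 lower under median centring and 126 higher and 18 lower under all 5 scalings. Its 326 genes ranged from 265 to 355 with each sample left out and stayed within 1.5 times under every alternative (227 with a 2-fold minimum, 288 to 423 for the others with all samples of the comparison), and 42 of 51 called named genes kept their call in all. The WT response ranged from 9 (without WT control 3) to 94 (without WT control 2), with 34 genes on common reference genes, 126 with array weights, 27 with both samples left out and 2 in a fit of its 6 samples alone, and 2 of 32 named genes (Birc5 and Rrm2) kept their call in all. For untreated kidneys, 0 genes passed except 79 with array weights and 22 without WT control 2 (range 0 to 22). KO NTS against WT NTS ranged from 129 (without WT NTS 3) to 329 (without WT NTS 1), with 373 genes with array weights, 345 with both samples left out, 141 in a fit of its 6 samples alone and 145 of at least 2-fold, and 36 of 62 named genes kept their call in all. The interaction ranged from 0 to 207 (without WT NTS 1), with 20 genes with median centring, 46 with quantile normalization, 44 without the variance trend, 291 with array weights, 9 on the positive controls and 212 with both samples left out. The array weights stopped before convergence, so their counts are uncertain. Of the lists, 0 passed with an estimated correlation in every comparison. With fry, which tests whether a list moves at all, counts in one direction were 7 in WT, 26 in KO, 0 untreated, 24 in treated kidneys and 1 for the interaction, and in either direction 16, 30, 0, 28 and 20. Lists with each sample left out ranged from 8 to 11 in WT, 6 to 8 in KO, 1 to 4 untreated, 5 to 11 treated and 3 to 7 for the interaction. With both samples left out they were 6 in WT, 1 untreated and 8 for the interaction; on the positive controls 1 untreated and 5 for the interaction; with median centring 7 for the interaction. The correlation of both responses was 0.47 with array weights and 0.48 (without WT NTS 1) to 0.77 (without WT control 1) with a sample left out. Some values near 0 were reversed. In KO, Cd44 was -0.0242, Il18 -0.48, Casp1 -0.33 and Cd4 -0.0361 with median centring, and Il18 was -0.66 and Casp1 -0.45 with quantile normalization. In treated kidneys, Cd44 was -0.0745, Casp1 -0.23 and Rrm2 -0.12 with median centring, Casp1 -0.34 with quantile normalization, and Il18 0.0075 on common reference genes, 0.13 on the positive controls, 0.01 without WT NTS 2, and from -0.165 (without KO NTS 3) to 0.0806 (without KO NTS 1) with a sample left out. Spp1 had a difference of 0 with quantile normalization by construction, being the highest gene in every sample. The cause of the other moves was not tested. With the replicate number as a block, 39 genes passed in WT, 318 in KO, 0 untreated, 212 treated and 72 for the interaction. The numbers did not pair the samples: 18 pairs had correlations of their deviations from -0.298 to 0.395, 3 of them over 0.1, and 3 of 12 samples correlated best with their own number. TMM and DESeq2 alternatives were not run because the values are not raw counts, and the second deposited table is identical, so it gave no value of its own. Signal near the floor limits low genes: 19 tested genes had a whole group at the floor.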

Other observations

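All paragraphs here report values chosen after the results were seen, with no new test. Of 11 genes of the Toll-like receptor list, 5 rose in KO kidneys after serum and the same number were higher in KO NTS than in WT NTS, also adjusted over the list alone. Tlr8 and Tlr2, receptors of RNA and of bacterial lipopeptides, were 3.91-fold and 4.07-fold higher in KO NTS than in WT NTS, and the shared adaptor Myd88 rose 2.08-fold in KO kidneys but was not called with median centring (log2 change 0.28). The list had a camera adjusted p of 0.14 and 0.167, so it did not stand above the panel, and with median centring 3 of its genes were higher and 3 lower in KO kidneys. Of 10 immediate early genes, 8 rose in KO kidneys (camera adjusted p = 0.0697; 5 with median centring), with the phosphatase gene Dusp5 4.93-fold higher, and 7 were higher in KO NTS than in WT NTS (camera adjusted p = 0.107; 4 with median centring), with Fosl1, a subunit of the AP-1 transcription factor, 3.30-fold higher. Of 23 genes of interleukin receptors and JAK-STAT signalling, 14 rose and 1 fell in KO kidneys, among them Stat3 (2.78-fold) and the interferon gamma receptor chain Ifngr1 (2.29-fold). That list had a camera adjusted p of 0.256, with 6 higher and 4 lower with median centring, where Ifngr1 was not called, and 6 and 5 with quantile normalization.

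Growth factor genes moved both ways in KO kidneys, with 7 of 22 higher and 6 lower, or 7 and 7 adjusted over the list alone, and 4 and 12 with median centring. Csf1 rose 4.10-fold, while Angpt1, a ligand of vascular stabilization, had a log2 change of -1.31 and Kdr, the main receptor of Vegfa, one of -1.30. Of 17 T cell markers, 1 rose in KO kidneys (Cd4, log2 change 0.74, adjusted p = 0.0445, and 0 adjusted over the list alone), and with median centring 10 of 16 T cell markers were called lower. Among 7 neutrophil markers, 3 rose in KO kidneys, including S100a8 and S100a9, subunits of calprotectin (3.04-fold and 3.51-fold). S100a8 and S100a9 lost their call with median centring and with quantile normalization, where 0 neutrophil markers were higher. In KO NTS against WT NTS, 0 neutrophil markers passed, with S100a8 at a log2 difference of 0.84 (adjusted p = 0.134).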
